A study of Homo sapiens with 12 samples.

How the data were processed

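The 12 libraries are amplicons of single guide RNAs (guides) from the genomic DNA of LNCaP cells, an androgen-sensitive human prostate adenocarcinoma line. Per the labels' protocols, the cells were infected at a multiplicity of 0.3 with TKOv3, a lentiviral library for genome-wide knockout with Cas9, selected with puromycin and split into 6 pools, 3 for control and 3 for treatment. Cells of each pool were taken just before the first treatment (T0) and at the end (TF). The culture lasted 63 days with a passage every 9 days. In each passage the cells adhered for 3 days and then had 6 days of 50 uM enzalutamide, an inhibitor of the androgen receptor, or the same volume of DMSO. Per the labels, 200 ng of DNA of each sample was sequenced.

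The deposited values are raw read counts per guide, 1 table per sample, with 71090 guides for 18053 genes and 142 control guides against LacZ (96), EGFP (22) and luciferase (24). The submitters' processing notes name cutadapt 1.16 and MAGeCK 0.5.7 without saying what each did, so how reads were trimmed and matched to guides is not known here. Library totals ran from 9289039 to 17250147 counts. Reads carry no molecular identifiers, so floors and counting intervals cover counting error only. The files give a position for each guide but name no genome build, and only 10.2% of the guides lie in the GRCh38.p14 span of their gene in the reference table. Positions are therefore given as in the files, with the build unknown, and that table served for names only. Of the gene names, 16700 were current symbols, 1271 were older names and 82 were unmatched. The names of the files are kept.

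Groups follow the labels: DMSO T0, enzalutamide T0, DMSO TF and enzalutamide TF, with 3 pools each. Guides needed a mean of at least 30 counts over the 6 T0 samples, which left 69708 guides and removed 1382. All 4 groups entered 1 fit in edgeR 4.0.16 (R 4.3.3) with TMM normalisation and the quasi-likelihood test. One-sided guide p-values were ranked, ranks above 0.25 were ignored, and the remaining ranks of each gene were combined by robust rank aggregation against 1000000 random rank sets. The smallest p this can give is 1e-06. Genes needed 2 or more guides, which left 17806, and control guides were left out. Benjamini-Hochberg adjustment ran over genes for each direction, and genes were called at 0.05. Every adjusted p of a single gene below comes from this edgeR and rank-aggregation test unless another is named.

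The size of a gene's change is the difference of group means of its mean log2 CPM over guides, with a prior count of 2. It is given relative to the median gene, because the median shifted by -0.86 between both final groups and by -0.86 between enzalutamide TF and its T0. Errors are standard deviations: over time, across 3 pairs of a TF and a T0 library of the same label and number, which share no pool by the correlations below; between arms, of the difference, as the root of the summed variances of the library values of each group compared. The standard error of limma 3.58.1 is not printed, since its pooled fit mixes quiet T0 libraries with far noisier final ones: the median gene's SD was 0.117 in DMSO T0, 0.155 in enzalutamide T0, 0.574 in DMSO TF and 1.11 in enzalutamide TF. The edgeR and camera p-values come from fits over the same 4 groups and share this limit. The common dispersion of guide counts ran from 0.0284 in DMSO T0 to 2.52 in enzalutamide TF. A gene with 0 counts in every enzalutamide TF library has a bound only, computed as the reference group's mean of summed guide CPM against a floor of 3 counts per library, with no subtraction of the median gene. The guide p-values measure the spread between pools of 1 cell line. The p of a gene measures how far the ranks of its guides agree, against random ranks. Camera's p compares a list with the other genes.

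The 5 contrasts were enzalutamide TF against DMSO TF, each TF group against its T0 group, the difference of those changes, and enzalutamide T0 against DMSO T0 as background. The choice of test, groups, gene lists and named genes was made before the data were examined. Named are, for each contrast and direction, the 10 called genes with the lowest p among those with at least 3 guides and all 3 pairs or, between arms, all 3 enzalutamide values in that direction; FOXA1, HOXB13, GRHL2, NR3C1, CDKN1A, MDM2, RB1, CDK4, TSC1, TSC2, NF1, KEAP1 and MYC whatever their values; and up to 4 members of each list with the lowest p in the direction described. Other names were chosen after their values were seen, which is said where they occur. Some of the genes and lists that were tested are not reported here.

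The 35 gene lists were tested with camera from limma on gene means, with a preset correlation of 0.01 and again with an estimated one, adjusted over the 35 lists of a contrast. They include cytosolic ribosomal proteins, proteasome subunits, cytosolic tRNA synthetases, spliceosome, DNA replication, mitochondrial ribosomal proteins, oxidative phosphorylation, androgen-induced genes, steroid metabolism and enzalutamide disposition, other steroid receptors, restraints and activators of PI3K-mTOR, restraints of the RB pathway, G1/S drivers, restraints and drivers of RAS-MAPK, Hippo kinases and partners, Wnt restraints, Mediator, BAF and PBAF, Polycomb, COMPASS and menin, homologous recombination and Fanconi, mismatch repair, cholesterol synthesis, KEAP1-NRF2, ferroptosis defence, ferroptosis drivers, effectors of mitochondrial apoptosis, apoptosis inhibitors, neuroendocrine and plasticity factors, and olfactory receptors. A gene can be in more than 1 list. The union of cytosolic ribosomal proteins, proteasome, spliceosome and DNA replication served as essential genes, and olfactory receptors as genes taken to be dispensable; both were compared by the area under the ROC curve in each such pair.

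Single values of 3 libraries against 3 were compared by two-sided exact permutation tests, whose smallest p is 0.1. To check which libraries share a pool, each guide's deviation from its group mean was correlated between T0 and TF libraries. The gene test was tested on simulated counts with library sizes scaled by the TMM factors, not the total counts, and 1 common spread per group. These factors were 1.45 to 1.56 at T0 and 0.479 to 0.614 in enzalutamide TF. The simulated T0 libraries were therefore deeper, and the simulated enzalutamide TF libraries shallower, than the real ones. Recovery at the real depth was not measured. There were 17806 genes and 50 genes changed at each log2 fold of -4, -2, 2 and 4. For DMSO TF against T0 it recovered 100, 60, 84 and 100% of them, with 3 false genes among 175 calls. For enzalutamide TF against T0 it recovered 20, 0, 14 and 72%, with 0 false among 53. For enzalutamide TF against DMSO TF it recovered 36, 2, 4 and 64%, with 1 false among 54. In camera, 0 of 100 simulated unchanged lists had a p under 0.05, and the changed list was called. The simulated guides were drawn independently, so this check could not show false lists from genes that vary together. The alternatives were other size factors (DESeq2 1.42.0, total counts, control guides, olfactory receptor guides), no filter or a minimum of 100, other rank truncations, at least 4 guides, only the groups compared, the replicate number or the labelled pool as a block, each replicate left out, DESeq2's guide test, and edgeR on summed guides, limma and fry as gene tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.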

Results

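The 12 libraries give read counts of guides that knock out genes in LNCaP cells, an androgen-sensitive prostate cancer line, before and after 63 days of culture with enzalutamide or DMSO. There were 4 groups with 3 pools each. They are DMSO T0, enzalutamide T0, DMSO final and enzalutamide final, where T0 was sampled just before the first treatment. Total counts of replicates 1, 2 and 3 were 14215478, 9289039 and 12983071 in DMSO T0, 11453788, 11795675 and 14638320 in enzalutamide T0, 11194107, 14314622 and 17250147 in DMSO final and 14357942, 10461135 and 12025154 in enzalutamide final. Median counts per guide were 157 ± 32.9, 158 ± 27.5, 90 ± 10.1 and 33 ± 9.64 in the 4 groups. The design text asks how guide abundance compares between the 2 treatments and times. Changes below are log2 values relative to the median gene. The sign ± gives an SD: over time, across 3 pairs of a final and a T0 library of the same label and number (n = 3); between arms, of the difference, with the spread of every group compared (3 libraries each). The adjusted p of a gene is from edgeR with rank aggregation over 17806 genes, and that of a list is from camera over 35 lists.

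The arm labels of the T0 and final libraries did not match. A pool's T0 and final library should share deviations over guides, taken from the mean of all 6 T0 libraries and from the final group mean. Yet the 6 pairs of the same label and number had Pearson correlations across 69708 guides of -0.00506 to 0.00265. Each of the 6 final libraries correlated best with the T0 library of its number in the other arm, at 0.128 to 0.204. The 24 pairs with different numbers lay between -0.104 and 0.00972. Of the 720 ways to assign T0 to final libraries, 1 gave a mean as high as this crossed one (exact permutation p = 0.00139). Guides are not independent replicates. Groups are kept as labelled, so that DMSO and enzalutamide mean the libraries labelled so. If the final libraries carry the exchanged labels, every direction between the 2 final groups below turns around and the arms change places in the comparisons over time. If the T0 libraries carry them, both stay. Pairs of the same label and number therefore share no pool, and each comparison over time sets a final group against T0 libraries of other pools.

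**Figure D1:**
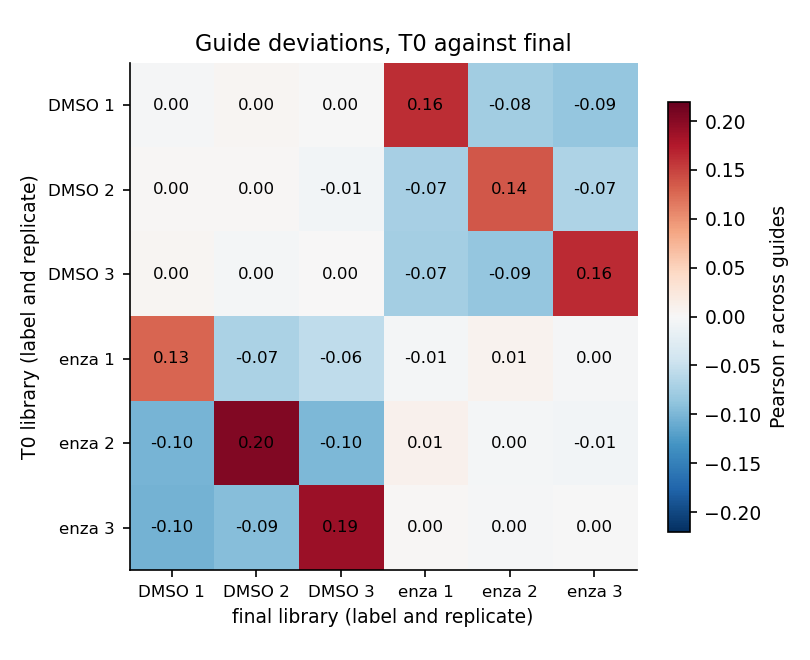
Pearson correlation across guides of the deviations, for each T0 library (vertical axis) against each final library (horizontal axis). Deviations are from the mean of all 6 T0 libraries at T0 and from the group mean in the final libraries. Colours and numbers give r. The 6 values from 0.13 to 0.20 pair equal numbers with opposite arm labels, and the same-label pairs lie near 0.

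Guides disappeared from the cultures, far more in the final enzalutamide libraries. On average 13244 ± 1506 guides (18.6%) had 0 counts there, against 1769 ± 190 (2.49%) in DMSO final, 383 ± 4.58 (0.539%) in DMSO T0 and 372 ± 9.17 (0.523%) in enzalutamide T0 (SD, n = 3). All 3 enzalutamide libraries lay above all 3 DMSO ones (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow), a ratio of 7.49, or 6.92 after thinning all libraries to 9289039 counts. Guides against the 161 essential genes, from the ribosome, proteasome, spliceosome and DNA replication lists, were at 0 in 49.0 ± 1.37% of cases in enzalutamide final and 11.0 ± 1.62% in DMSO final. Guides against 329 olfactory receptor genes were at 0 in 10.3 ± 1.26% and 0.104 ± 0.0452%, and the 134 tested control guides in 14.7 ± 1.55% and 0.498 ± 0.862%, the latter from 2 guides in DMSO final replicate 1. The top 1% of guides held 28.7 ± 5.36% of the reads in enzalutamide final and 21.0 ± 4.12% in DMSO final (exact permutation p = 0.2), against 3.05 ± 0.0299% in DMSO T0 and 4.13 ± 1.85% in enzalutamide T0, where replicate 1 had 6.27%. Replicate libraries had Spearman correlations of 0.818 to 0.885 at T0, 0.436 to 0.454 in DMSO final and 0.288 to 0.303 in enzalutamide final.

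**Figure D2:**
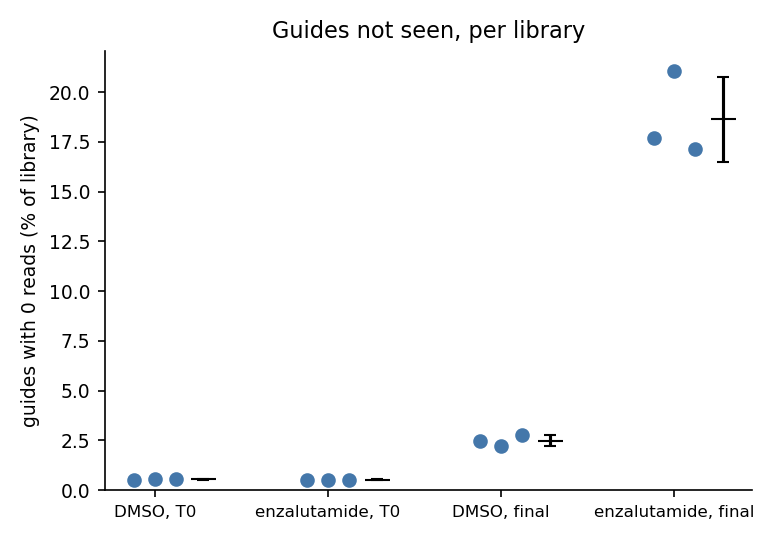
Share of guides with 0 reads (vertical axis, % of the library) in the 4 groups; points are libraries, and the bar beside them is the mean with its SD (n = 3). The 3 final enzalutamide libraries lie between 17.1 and 21.1%, and the 3 final DMSO libraries between 2.22 and 2.76%.

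In the final libraries labelled DMSO, guides against 205 genes fell from T0 and against 0 genes rose. Among the lowest p-values were those of SDHB of respiratory complex II (-4.17 ± 0.78), RPE of the pentose phosphate pathway (-3.90 ± 0.51), the vesicle-tethering factor TRAPPC1 (-3.89 ± 0.63) and GCLC, which starts glutathione synthesis (-3.28 ± 0.34), all with adjusted p = 0.00356 in edgeR with rank aggregation. MARS2, the mitochondrial methionyl-tRNA synthetase (-4.10 ± 0.74), ALG1 of N-glycosylation (-3.64 ± 0.27), the helicase DDX49 (-2.95 ± 0.18), STRAP (-4.27 ± 0.25) and the elongator subunit ELP5 (-4.24 ± 0.45) followed at 0.00411. Each of these genes was lower in 3 of 3 label pairs, which the rule for naming required. The 0 count of genes that rose, from edgeR with rank aggregation, compares with 989 genes at an unadjusted p under 0.05, where chance gives 890, and with 7 in limma.

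Gene groups of basic cell functions fell in DMSO. The median of 49 cytosolic ribosomal proteins fell by 1.47 (camera adjusted p = 7.76e-15), of 31 proteasome subunits by 1.37 (1.48e-17), of 41 DNA replication genes by 1.37 (1.55e-18), of 40 spliceosome genes by 1.05 (1.72e-10), of 20 cytosolic tRNA synthetases by 1.24 (2.00e-10), of 75 mitochondrial ribosomal proteins by 1.2 (7.07e-21), of 92 oxidative phosphorylation genes by 1.26 (7.07e-21) and of 33 Mediator genes by 1.10 (8.59e-09). Members called over all genes, and adjusted over the list alone, were 3 and 14 for the cytosolic ribosome, with RPL18 (-2.53 ± 0.94) and RPL14 (-2.88 ± 0.10), 1 and 10 for the proteasome, with PSMB7 (-3.15 ± 0.83), and 3 and 10 for DNA replication, with RFC5 (-3.03 ± 0.49), RRM1 (-2.59 ± 0.39) and MCM5 (-2.60 ± 1.19). They were 2 and 8 for the spliceosome, with DHX15 (-3.07 ± 0.29) and SNRPB (-1.71 ± 0.62), 1 and 7 for tRNA synthetases, with YARS (-2.24 ± 0.06), 5 and 25 for the mitochondrial ribosome, with MRPL53 (-3.65 ± 0.74), 11 and 27 for oxidative phosphorylation, with CYC1 (-3.24 ± 0.85) and ATP5A1 (-3.32 ± 0.17), and 1 and 8 for Mediator, with MED30 (-2.89 ± 0.79). With a T0 minimum of 100 counts per guide the lists still passed, but the medians were -0.51 for cytosolic ribosomal proteins (0.00550), -0.29 for the spliceosome (0.0241) and -0.83 for DNA replication.

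Regulators of prostate cell identity and growth signalling were also among the genes that fell in DMSO. The epithelial transcription factors GRHL2 (-2.99 ± 0.34, adjusted p = 0.0157 in edgeR with rank aggregation) and SPDEF (-2.11 ± 0.60, 0.0299) fell, while HOXB13 was at -1.98 ± 0.28 (0.0690) and FOXA1 at -0.53 ± 1.26. The PI3K-mTOR restraints TSC1 (-2.82 ± 0.44) and TSC2 (-3.20 ± 0.52), which hold back mTOR, fell, as did the activators MTOR (-3.03 ± 0.47), PDPK1 (-2.46 ± 0.47) and AKT1 (-2.14 ± 0.50). The 19 restraints had a median of -0.62 (camera adjusted p = 0.000654; 2 called, 5 adjusted over the list alone) and the 25 activators of -0.45 (0.000604; 3 and 3), so members of opposite sign in the pathway moved alike. The Polycomb repressive genes EZH2 (-2.41 ± 0.29), EED (-2.37 ± 0.92) and SUZ12 (-2.96 ± 0.31) fell in a list of 21 with a median of -0.97 (3.53e-05; 3 and 4), and PAXIP1 (-3.53 ± 0.41), DOT1L (-2.94 ± 0.67) and DPY30 (-2.67 ± 0.35) in the 17 COMPASS and menin genes with a median of -0.44 (0.00112; 3 and 5; -1.10 without DMSO final replicate 2 and -0.04 without replicate 3). MYC (-2.98 ± 0.71) and CCNA2 (-2.24 ± 0.29) fell among 18 G1/S drivers with a median of -0.67 (7.83e-06; 2 and 4), where CDK4 was at -1.98 ± 0.09. With a T0 minimum of 100 counts the activators did not pass (-0.26, 0.104), and the medians were -0.43 for G1/S drivers and -0.82 for COMPASS and menin.

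Lists for redox, chromatin, repair and lipid genes fell in DMSO too. Their medians were -1.0 for 13 ferroptosis defence genes (camera adjusted p = 2.27e-07; GCLC called, 6 adjusted over the list alone), -0.60 for 12 KEAP1-NRF2 genes (0.000605; 2 and 2, with KEAP1 at -3.04 ± 0.67), -0.59 for 23 BAF and PBAF genes (4.44e-07; 0 and 0; -0.96 without DMSO final replicate 1), -0.57 for 29 homologous recombination and Fanconi genes (0.000428; 1 and 1) and -0.36 for 26 cholesterol synthesis genes (0.0203; 1 and 5, HMGCS1 at -2.05 ± 0.41). The 329 olfactory receptors had a median of 0.12 (0.00939; 0 and 0). Each of the 21 list calls in DMSO held with an estimated correlation. With a T0 minimum of 100 counts the cholesterol list (-0.03, 0.468) and olfactory receptors (0.08, 0.0791) did not pass and KEAP1-NRF2 had -0.26; the cholesterol list was also lost with total counts (0.0809). NF1 guides were at 1.12 ± 0.86 (adjusted p = 0.919 in edgeR with rank aggregation), CDKN1A at 0.67 ± 0.61, RB1 at 0.19 ± 0.38, NR3C1 at 0.15 ± 0.78 and MDM2 at -0.66 ± 0.45.

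The DMSO calls rest in part on single libraries and on the gene test. By edgeR's guide test alone, 0 guides passed at an adjusted p of 0.05. Without DMSO final replicate 1 the number of genes that fell was 120 instead of 205, edgeR on summed guides called 0 and a T0 minimum of 100 counts gave 66. Without 1 replicate the adjusted p rose to at most 0.105 for GRHL2 (DMSO final replicate 2), 0.103 for TSC1 (DMSO final replicate 1), 0.0937 for TSC2 (DMSO final replicate 3), 0.0924 for KEAP1 (DMSO final replicate 2) and 0.0542 for MYC (DMSO final replicate 2), at changes of -2.81, -2.49, -3.06, -2.85 and -3.04. The T0 minimum of 100 also ended the calls of STRAP, GRHL2 and TSC1, total counts that of TSC2, and control guides as reference or no filter that of KEAP1. The cholesterol list had a camera adjusted p of 0.0666 without DMSO final replicate 2.

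In the final enzalutamide libraries, guides against 42 genes fell from T0 and against 0 rose. Guides of several of these genes were absent from all 3 final libraries, which gives only a bound. Against T0 they were lower by at least 118-fold for PET117, an assembly factor of cytochrome c oxidase, 67.4-fold for MRPS34 of the mitochondrial ribosome, 40.8-fold for the transcription factor TBX3, 39.2-fold for the tubulin TUBB and 36.9-fold for POLR2E, a subunit shared by RNA polymerases. DPAGT1, which starts N-glycosylation (-4.35 ± 0.33), SEC63 of the endoplasmic reticulum translocon (-4.19 ± 0.67) and MGEA5, the O-GlcNAcase that removes O-GlcNAc from proteins (-4.11 ± 0.36), fell as well. Guides of the condensin gene NCAPH2 had 1 count in 3 final libraries against 1530 at T0, a normalised ratio of 520 (95% counting interval 93.2 to 20565), or 330 without enzalutamide final replicate 1; without replicate 3, 0 counts are left. The adjusted p of these genes in edgeR with rank aggregation ran from 0.00890 for TUBB to 0.0160 for MGEA5. Each moved the same way in 3 of 3 label pairs, which the rule for naming required.

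Of the genes fixed in advance, TSC1 fell in enzalutamide (-4.11 ± 0.48, adjusted p = 0.0228 in edgeR with rank aggregation), and the others named here did not pass. HOXB13 was at -3.09 ± 0.38 (0.0618), TSC2 at -3.52 ± 0.70 (0.0944), KEAP1 at -4.33 ± 1.10 (0.149), CDK4 at -3.10 ± 0.91 (0.190), FOXA1 at -2.91 ± 0.96 (0.370), GRHL2 at -2.92 ± 0.74 (0.372), MDM2 at -1.47 ± 1.37 and NR3C1 at -0.17 ± 2.09. MYC guides were absent, at least 18.4-fold below T0 (0.0659). On the other side, RB1 was at 3.47 ± 0.45 (0.540), CDKN1A at 0.40 ± 0.06 and NF1 at 0.31 ± 1.44. The lowest adjusted p for a rise belonged to ARRDC3 (4.38 ± 1.74, 0.0890), named after its value was seen. The 0 genes that rose in edgeR with rank aggregation compare with 996 at an unadjusted p under 0.05 and 136 in limma.

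**Figure D3:**
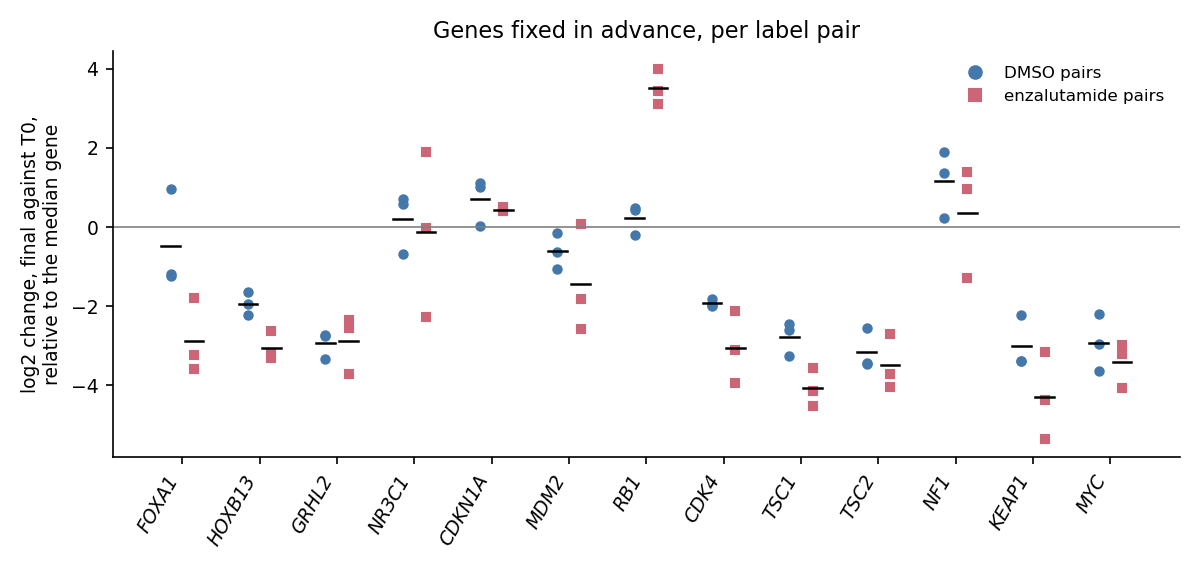
Change of 13 genes fixed in advance between T0 and the final libraries (vertical axis, log2 relative to the median gene); points are pairs of a T0 and a final library of the same label and number, and short lines are means of 3. RB1 lies near 0.19 in DMSO and 3.47 in enzalutamide, while TSC1 and TSC2 lie below 0 in all 6 pairs; none of the rises passed the test.

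The gene lists that fell in DMSO mostly fell in enzalutamide too. Medians were -2.23 for COMPASS and menin (camera adjusted p = 1.99e-06), with DOT1L called, -2.11 for mitochondrial ribosomal proteins (7.62e-17), with MRPS14 (-3.33 ± 0.66), and -1.84 for the spliceosome (2.59e-10), with SF3B4 (-3.31 ± 0.94). Of the 17 COMPASS and menin genes, 1 had 0 counts in every final enzalutamide library and so has a bound only. The medians were -2.07 for the proteasome (4.81e-08), -1.88 for cytosolic ribosomal proteins (2.59e-10), -1.75 for tRNA synthetases (1.40e-06), -1.55 for Mediator (4.81e-08), -1.45 for oxidative phosphorylation (4.65e-09) and -1.31 for DNA replication (8.37e-08), with 0 members called in these 6. Further medians were -1.92 for ferroptosis defence (1.24e-05; -1.24 without enzalutamide final replicate 2), -1.86 for Polycomb (8.48e-05), with SUZ12 called (-3.57 ± 0.23), -1.30 for PI3K-mTOR activators (0.00115), -1.14 for homologous recombination and Fanconi (0.000837), -0.99 for BAF and PBAF (0.00456; -0.62 without enzalutamide final replicate 2), -0.88 for PI3K-mTOR restraints (0.00970) and -0.62 for G1/S drivers (0.00602; -0.94 without enzalutamide final replicate 2). Adjusted over the list alone, 28 mitochondrial ribosomal, 13 Mediator, 8 cytosolic ribosomal, 8 proteasome, 8 oxidative phosphorylation, 7 Polycomb, 7 PI3K-mTOR activator, 6 ferroptosis defence, 5 spliceosome, 5 COMPASS and menin, 4 G1/S, 2 PI3K-mTOR restraint, 1 DNA replication (RPA1) and 1 BAF and PBAF gene (ARID1A) passed. The lists of 18 neuroendocrine and plasticity factors (0.63, 0.0196) and of olfactory receptors (0.44, 0.00159) rose against the median gene, with 0 members called. Each of the 19 list calls held with an estimated correlation; with the genes at 0 set at their bounds, the medians of the ribosomal, G1/S and COMPASS lists stayed at -1.88, -2.11, -0.62 and -2.23. With a T0 minimum of 100 counts PI3K-mTOR activators (-0.80), G1/S drivers (-0.44), BAF and PBAF (-0.91) and neuroendocrine factors (0.58) did not pass, and cytosolic ribosomal proteins had -1.14 and Polycomb -0.96. With the median over guides the spliceosome had -2.89, and neuroendocrine factors did not pass (0.34).

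**Figure D4:**
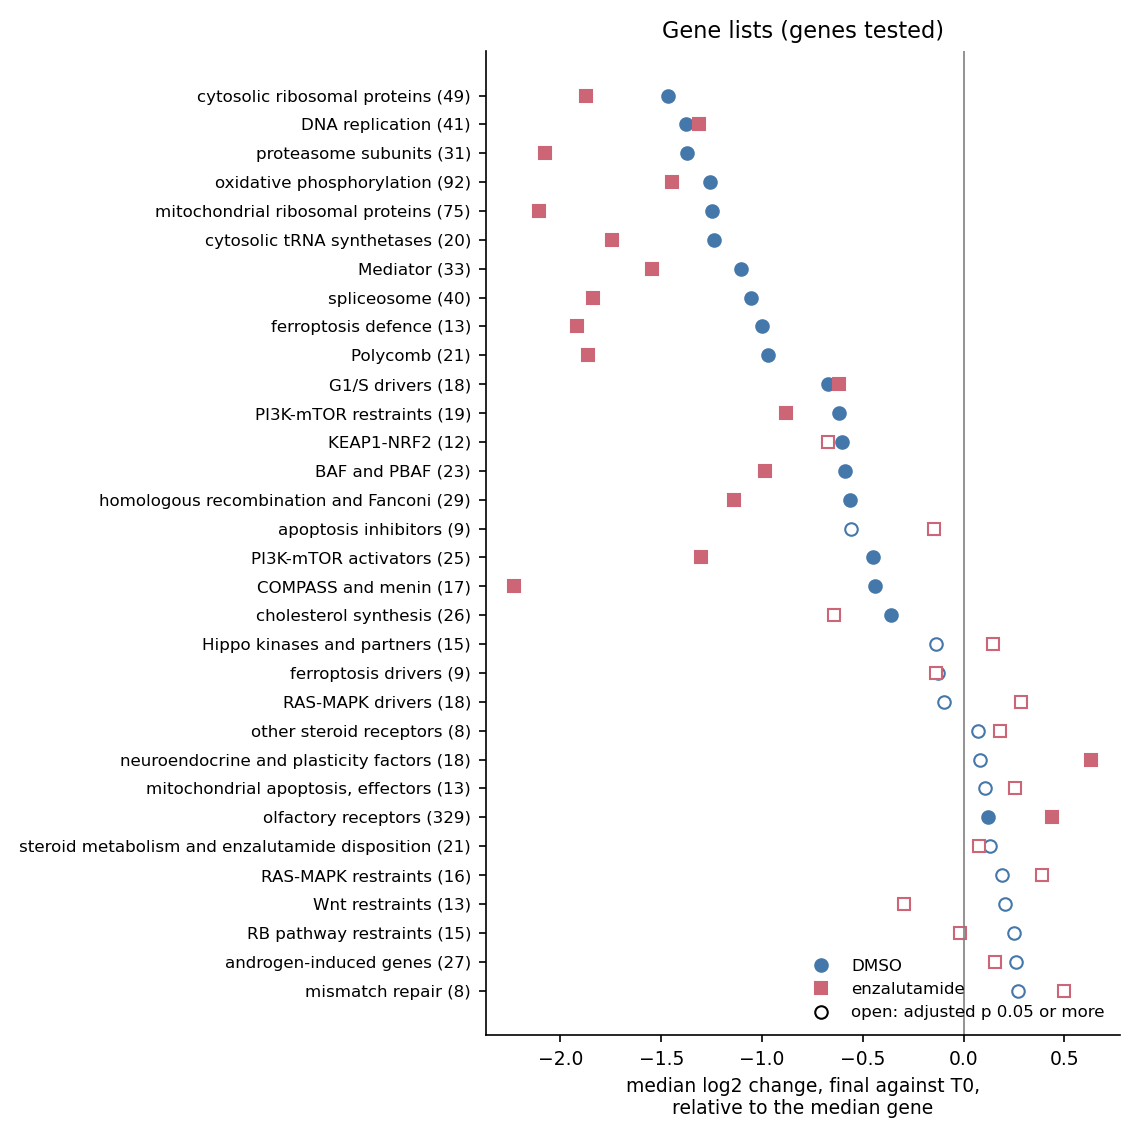
Median log2 change of gene lists between T0 and the final libraries, relative to the median gene (horizontal axis), for DMSO (circles) and enzalutamide (squares), with the number of genes tested beside each name; filled symbols passed at a camera adjusted p under 0.05. COMPASS and menin lies at -0.44 in DMSO and -2.23 in enzalutamide.

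Further lists did not pass in either arm. Their medians in DMSO and enzalutamide were 0.26 and 0.16 for androgen-induced genes, 0.13 and 0.08 for steroid metabolism and enzalutamide disposition, 0.07 and 0.18 for other steroid receptors, 0.25 and -0.02 for RB pathway restraints, 0.19 and 0.39 for RAS-MAPK restraints, and -0.10 and 0.29 for RAS-MAPK drivers. They were -0.14 and 0.15 for Hippo kinases, 0.21 and -0.30 for Wnt restraints, 0.27 and 0.50 for mismatch repair, -0.13 and -0.14 for ferroptosis drivers, 0.11 and 0.26 for effectors of mitochondrial apoptosis and -0.56 and -0.15 for apoptosis inhibitors. Neuroendocrine factors had 0.08 in DMSO (camera adjusted p = 0.332). In enzalutamide, KEAP1-NRF2 (camera adjusted p = 0.0869, median -0.67) and cholesterol synthesis (0.226, median -0.65) did not pass. Camera's direction opposed the median, with no call, for RAS-MAPK drivers, ferroptosis drivers and other steroid receptors in DMSO, and for steroid metabolism, RB restraints, Hippo kinases, apoptosis effectors and apoptosis inhibitors in enzalutamide.

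Fewer genes were called in enzalutamide when 1 final library was left out. The values of the called genes named here moved by less than 1.5 times, except for NCAPH2. Its ratio of 520 was 330 without enzalutamide final replicate 1, and 0 counts were left without replicate 3. Without enzalutamide final replicate 1, 2 or 3 the number of genes that fell was 0, 17 and 5. The genes of lowest p named above had adjusted p from 0.0712 to 0.177 without replicate 1 in edgeR with rank aggregation, and the adjusted p of TSC1 was 0.134, 0.127 and 0.197 without replicates 1, 2 and 3, at changes of -4.43, -3.92 and -4.08. MGEA5 was at -4.10, -4.33 and -3.99 in the same order. With a T0 minimum of 100 counts the calls of NCAPH2, DPAGT1, MGEA5 and TSC1 ended. The neuroendocrine list had adjusted p = 0.0916 without enzalutamide final replicate 3, and the PI3K-mTOR restraints 0.118 without replicate 1.

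The genes that fell overlapped between arms. Of 205 genes in DMSO and 42 in enzalutamide, 23 were shared, where independent lists would share 0.484 (Fisher's exact p = 2.66e-34), and the arms shared no library, although 1 fit gave the spread of both. Among the shared genes were the chromatin genes DOT1L and SUZ12, the luminal transcription factor SPDEF, TSC1, VHL, DPAGT1 and MRPS34. Of the 205, 203 lay below the median gene in enzalutamide, and of the 42, 41 lay below it in DMSO. Across genes, which are not independent replicates, both changes had Pearson's r = 0.52 and Spearman's rho = 0.38. Essential genes were told from olfactory receptors with an area under the ROC curve of 0.858 ± 0.0124 in DMSO and 0.844 ± 0.00917 in enzalutamide (exact permutation p = 0.2), while the gap between their medians was -1.45 ± 0.11 and -2.21 ± 0.15 (exact permutation p = 0.1, the smallest possible).

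Between the final libraries, guides against 2 genes were lower with enzalutamide than with DMSO and against 0 were higher. MGEA5, the O-GlcNAcase (guides at 103563613 to 103577723 on chromosome 10, build not given), was at -4.92 ± 0.78 (adjusted p = 0.0178 in edgeR with rank aggregation), with 4 of 4 guides lower and 3 of 3 enzalutamide libraries below the DMSO mean. The rule for naming required at least 3 guides and all 3 libraries in that direction. PET117, for cytochrome c oxidase assembly (18118599 to 18118693 on chromosome 20), had 0 counts for 4 guides in 3 enzalutamide libraries and 551 in DMSO, at least 32.9-fold lower (0.0445). ARRDC3, an arrestin-domain gene named after its value was seen, was at 4.99 ± 1.76 and did not pass (0.0534). The 0 genes that were higher in edgeR with rank aggregation compare with 931 at an unadjusted p under 0.05, where chance gives 890, and with 117 in limma; for lower genes the numbers were 1070 and 3905. Both calls ended without any of the 3 enzalutamide final replicates (adjusted p of 0.510, 0.361 and 0.443 for MGEA5, and 0.585, 0.361 and 0.538 for PET117), although MGEA5 stayed at -4.91, -5.13 and -4.80 and the bound of PET117 at 31.1, 37.8 and 30.7-fold. PET117's call also ended without DMSO final replicate 3 (0.0890), with total counts (0.0801) and with the replicate number as a block (0.0997). Without DMSO final replicate 1 the count was 5, without DMSO final replicate 3 it was 1, and DESeq2's guide test called 0; under total counts the lower and higher genes were 1 and 1 instead of 2 and 0.

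Of the gene lists, 5 were lower in the final enzalutamide libraries than in the DMSO ones. Mitochondrial ribosomal proteins had a median of -0.73 (camera adjusted p = 2.13e-05) with 65 of 75 below the median gene, for example MRPL33 (-1.84 ± 1.05) and MRPL41 (-2.17 ± 1.77). The spliceosome had -0.97 (0.00219) with 32 of 40 below, such as EFTUD2 (-2.44 ± 1.75) and U2AF2 (-2.39 ± 1.49). COMPASS and menin had -1.08 (0.00563) with 14 of 17 below, such as NCOA6 (-2.53 ± 0.47) and HCFC1 (-2.03 ± 2.29). Mediator had -0.78 (0.0122) with 26 of 33 below, such as MED14 (-2.27 ± 1.06) and CCNC (-2.49 ± 1.11). Cytosolic ribosomal proteins had -0.59 (0.0419) with 36 of 49 below. Of these 49 genes, 3 had 0 counts in every enzalutamide final library, and with genes at 0 set at their bounds the median was -0.55. With an estimated correlation, the mitochondrial ribosome (adjusted p = 0.00607) and the spliceosome (adjusted p = 0.0380) passed, and COMPASS and menin (adjusted p = 0.119), Mediator (adjusted p = 0.0736) and cytosolic ribosomal proteins (adjusted p = 0.277) did not. Over all genes 0 members of any of the 5 were called, and adjusted over the list alone 1 mitochondrial ribosomal, 3 spliceosome, 3 COMPASS and menin, 2 Mediator and 0 cytosolic ribosomal genes passed. Without enzalutamide final replicate 3 only the mitochondrial ribosome stayed, with adjusted p of 0.0734 for the spliceosome, 0.110 for COMPASS and menin, 0.243 for Mediator and 0.394 for cytosolic ribosomal proteins. Mediator was also lost without enzalutamide final replicate 1 (0.0964), and cytosolic ribosomal proteins without enzalutamide final replicate 2 (0.0765) or DMSO final replicate 3 (0.0629). With total counts only the mitochondrial ribosome stayed (-0.51), and the medians of the spliceosome, COMPASS and menin, Mediator and cytosolic ribosomal proteins were -0.59, -0.79, -0.50 and -0.25. The T0 minimum of 100 ended Mediator (-0.88) and cytosolic ribosomal proteins (-0.88), which no filter ended too (-0.42). With the median over guides the mitochondrial ribosome, spliceosome and Mediator had -1.48, -1.61 and -1.34.

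Transcription factors of the prostate and growth-control genes fixed in advance did not differ between the final groups by the gene test. GRHL2 was at 0.15 ± 0.89, HOXB13 at -1.07 ± 0.28 and FOXA1 at -2.31 ± 1.63 (adjusted p = 0.528 in edgeR with rank aggregation). SPDEF, not among the genes fixed by name, was at -1.86 ± 0.96 (0.283). RB1, the restraint of the G1/S step, was at 3.30 ± 0.45 (0.605), and it alone passed adjusted over the 15 RB pathway restraints, which had a median of 0.11 (camera adjusted p = 0.318). CDKN1A was at -0.17 ± 0.68, MDM2 at -0.66 ± 1.2, CDK4 at -0.97 ± 0.94, NR3C1, the glucocorticoid receptor, at -0.28 ± 2.29, NF1 at -1.16 ± 1.52, KEAP1 at -1.42 ± 1.15, TSC1 at -1.46 ± 0.78 and TSC2 at -0.39 ± 0.92. MYC guides were at 0 in enzalutamide and had 22 counts in DMSO, 15 of them in replicate 1, too few for a bound. Neuroendocrine factors had a median of 0.72 and Polycomb genes of -0.51, each with a camera adjusted p of 0.0801. No other list passed. Camera's direction opposed the median for BAF and PBAF (0.22), KEAP1-NRF2 (0.22), DNA replication (0.01) and androgen-induced genes (-0.08), and the mean did for cholesterol synthesis (median 0.11, mean -0.06). In the simulation, the test found 2% of genes lowered and 4% of genes raised by 2 log2 units. At 4 log2 units it found 36% of genes lowered and 64% of genes raised. A gene without a call can therefore still differ by this much. The simulated enzalutamide final libraries were shallower than the real ones, so these shares may differ at the real depth.

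The change over time differed between arms for 8 genes, all lower with enzalutamide. MGEA5 differed by -4.88 ± 0.81 (adjusted p = 0.0178 in edgeR with rank aggregation). ACD of the telomere shelterin complex differed by -4.25 ± 1.35, FAU, a ribosomal protein precursor, by -3.20 ± 0.68 and SUPV3L1, a mitochondrial RNA helicase, by -3.11 ± 1.13 (all 0.0490). The change of TKT, transketolase of the pentose phosphate pathway, differed too (0.0490). TKT had 3 counts in the final enzalutamide libraries and 1406 in DMSO, 1069 of them in replicate 2. In DMSO final, the guide at 53274346 on chromosome 3 had 299 and 666 counts in replicates 1 and 2. The guide at 53276232 had 378 in replicate 2. The mean log2 CPM of TKT over guides was 2.61 ± 0.06 in DMSO T0 and 0.69 ± 1.91 in DMSO final. The normalised ratio of the summed counts, most of them from these guides, was 268 (95% counting interval 91.6 to 1302). It was 97 without DMSO final replicate 2, 419 without DMSO final replicate 3, 510 without enzalutamide final replicate 1 and 167 without enzalutamide final replicate 3. On the mean over guides, the change of TKT differed by -2.56. The changes of PET117 (0.0445), RCOR1 of the CoREST corepressor and the telomere helicase RTEL1 (both 0.0490) differed as well. Their guides were at 0 in enzalutamide final. Against DMSO final they were lower by at least 32.9-fold for PET117, 37.9-fold for RCOR1 and 14.9-fold for RTEL1. The bound of RCOR1 was 16.2-fold without DMSO final replicate 3. These folds and the ratio of TKT compare the final groups, where PET117 was called and TKT, RCOR1 and RTEL1 were not. The 0 genes with a higher change in edgeR with rank aggregation compare with 938 at an unadjusted p under 0.05 and 5 in limma. The same 5 lists differed, with medians of -0.77 for the mitochondrial ribosome (camera adjusted p = 1.76e-05), -0.84 for the spliceosome (0.00225), -1.14 for COMPASS and menin (0.00476), -0.78 for Mediator (0.0119) and -0.63 for cytosolic ribosomal proteins (0.0119), with adjusted p = 0.00577, 0.0384, 0.112, 0.0771 and 0.236 with an estimated correlation. The count of genes was 0 without any 1 of the 3 enzalutamide final replicates, 5 without DMSO final replicate 1, and 2 without DMSO final replicate 2 or 3, DMSO T0 replicate 3, or enzalutamide T0 replicate 1 or 2; it was 2 with the labelled pool as a block and 1 lower and 1 higher under total counts. Without DMSO T0 replicate 1 or enzalutamide T0 replicate 2, 1 gene had a higher change, and without enzalutamide final replicate 3 the lists were 1. MGEA5 stayed at -4.88, -5.10 and -4.77 without enzalutamide final replicates 1, 2 and 3. With total counts only the mitochondrial ribosome differed among lists (-0.51). The T0 minimum of 100 ended Mediator and cytosolic ribosomal proteins, and no filter (-0.38) or crossed T0 arms (-0.45) ended the latter.

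At T0, before any treatment, the arms served as background. No gene differed by edgeR with rank aggregation (0 lower and 0 higher, with 931 and 961 at an unadjusted p under 0.05 and 0 in limma). The fixed genes lay between -0.33 ± 0.46 (NF1) and 0.41 ± 0.61 (MYC). Of the 35 lists, cytosolic ribosomal proteins were called with a median of 0.07 (camera adjusted p = 0.0437; adjusted p = 0.527 with an estimated correlation), a value that ran from -0.01 without enzalutamide T0 replicate 1 to 0.13 without enzalutamide T0 replicate 2. The call ended without DMSO T0 replicate 2 or 3 or enzalutamide T0 replicate 1 (0 lists), and without enzalutamide T0 replicate 2 or 3 there were 2. Mitochondrial ribosomal proteins (0.02), the spliceosome (0.01), Mediator (0.00) and COMPASS and menin (0.03) were close to the median gene.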

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

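The tests of a kept arm label, of exchanged labels, of selection alone on control guides, of an equal median count of a guide and of the trend across lists were chosen only after the result was seen, and so were the alternatives with crossed T0 arms.

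The results listed here drew attention because the change over time differed between the arms by a test of the difference itself. Relative to the median gene, the difference was -4.88 for MGEA5, -4.25 for ACD, -3.20 for FAU, -3.11 for SUPV3L1, -2.90 for RCOR1, -3.20 for PET117, -2.56 for TKT (-1.69 without DMSO final replicate 2) and -1.97 for RTEL1, where RCOR1, PET117 and RTEL1 had no reads in the final enzalutamide libraries, so that their fitted values are no bounds. The lists differed by a median of -0.63 for cytosolic ribosomal proteins, -0.84 for the spliceosome, -0.77 for mitochondrial ribosomal proteins, -0.78 for Mediator and -1.14 for COMPASS and menin. With an estimated correlation, only the spliceosome and mitochondrial ribosomal proteins still passed in camera. Groups of 3 libraries were not tested for single libraries far from the rest.

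The T0 and final libraries matched across arms. The tables argue against kept labels, since the highest same-label correlation was 0.00265. They also argue against reads carried over from T0 into final libraries. The lowest matched correlation was 0.113 among the guides above the median final level, where a few such reads count little. Reads carried over from final into T0 libraries were not tested, since they would act most on these same guides. An exchange of the arm labels of all 3 numbers between T0 and final libraries may account for the match, whose lowest correlation was 0.128. Which of both sets carries the exchange stays open, and no biological explanation was tested. With the T0 arms crossed and no block, 5 genes had a lower change in enzalutamide instead of 8. With the crossed pool as a block, which uses this match, the number was lower still.

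More guides were lost in the final enzalutamide than in the final DMSO libraries. Reads taken by expanded guides and a lower depth of the typical guide do not account for it, since the ratio was 6.73 at equal total counts outside the top 1% of guides and 6.10 at an equal median count of a guide. Nor does selection against targeted genes alone, since olfactory receptor guides were lost 98.5 times as often and control guides 29.5 times. Both ratios rest on few lost guides in DMSO final. Olfactory receptor guides at 0 were 0.0782 to 0.156% of those tested there, and the ratio was 87.6 to 131 with 1 library left out. Control guides at 0 were 2 guides in DMSO final replicate 1 (0 without that replicate, and a ratio of 19.7 without DMSO final replicate 2 or 3). Random loss of clones may account for part of it, since olfactory receptor and control guides were lost from 2 of the enzalutamide pools in 109 cases, where independent loss gives 91.6, a ratio of 1.19. Whether the drug or a smaller number of cells led to such a loss stays open, because cell numbers are not in the deposited counts.

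Guides of mitochondrial ribosomal proteins and of the spliceosome were lower in the final enzalutamide than in the DMSO libraries. Low T0 abundance does not account for it, since the medians lay at percentiles 0 and 0.07 of 10000 random lists matched on T0 level. A deeper fall of every depleted gene cannot be told apart from an effect on these lists. After removing the trend over genes, the medians lay at percentile 0 for both lists, the outcome set in advance against such a deeper fall. That bound may be too narrow, since the slope over genes was 0.827, against 1.41 and 1.42 over lists. Noise in the DMSO change could flatten the slope over genes, which was not measured. Around the trend over lists they lay at -0.30 and -0.31, and 7 and 6 of the other 34 lists were as low.

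Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and the real split is among them. Between the final groups, 1 split called as many genes (2, highest other 0) and 1 as many lists (5, highest other 0). In DMSO, 1 split called as many genes (118 in a fit of these groups alone, highest other 1) and 1 as many lists (21, highest other 10). In enzalutamide, 1 split called as many genes (52 in such a fit, highest other 0) and 1 as many lists (19, highest other 11). For the difference of the changes, 1 split called as many genes (8, highest other 1) and 1 as many lists (5, highest other 1). At T0, 10 splits called as many genes (0, highest other 1) and 8 as many lists (1, highest other 2).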

How the results depend on the processing

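The tests with crossed T0 arms, with limma on centred gene means (all groups or only those compared) and, for lists, with the median over guides were chosen only after the result was seen. No called gene changed sign and no called list changed the direction of its test, although the median of cytosolic ribosomal proteins at T0, 0.07, was -0.01 without enzalutamide T0 replicate 1. Values without a call did change sign, among them GRHL2, NR3C1, TSC2, CDKN1A and MYC between the final groups, and DNA replication there, whose median of 0.01 became -0.89 with the median over guides (camera adjusted p = 0.0144).

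Between the final groups the lower and higher genes, 2 and 0, were 1 and 1 with total counts, 458 and 376 with edgeR on summed guides, 3905 and 117 with limma, 557 and 488 with limma on centred gene means and 3773 and 210 with fry. The lower genes were 1 with the replicate number as a block, 0 with DESeq2's guide test, 0 with centred limma on only the groups compared, and 0 to 5 without 1 replicate; the higher genes were 1 with at least 4 guides. Limma on gene means without centring and fry also test the shift of all genes, whose median was -0.86.

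In DMSO, 205 genes fell and 0 rose. The first number was 66 with at least 100 T0 counts, 118 with only the groups compared, 0 with edgeR on summed guides and 120 to 217 without 1 replicate. The pair was 420 and 7 with limma, 423 and 8 centred, 975 and 99 centred with only the groups compared and 602 and 54 with fry, and 1 rose with a block by pool and crossed T0 arms.

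In enzalutamide, 42 fell and 0 rose. The first number was 10 with at least 100 T0 counts and 0 to 44 without 1 replicate. The pair was 26 and 1 with total counts, 333 and 73 with edgeR on summed guides, 4674 and 136 with limma, 1621 and 851 centred, 619 and 91 centred with only the groups compared and 4562 and 263 with fry.

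For the difference of the changes, 8 genes were lower and 0 higher. The pair was 1 and 1 with total counts, 563 and 5 with limma and 1258 and 50 with fry. The lower genes were 2 with olfactory receptor guides as reference, 2 without a filter, 3 with at least 100 T0 counts, 2 with a block by labelled pool, 2 with that block and crossed T0 arms, 5 crossed with no block, 2 with DESeq2's guide test, 2 with edgeR on summed guides, 1 with centred limma, 1 with that on only the groups compared and 0 to 8 without 1 replicate; the higher genes were 1 with at least 4 guides and 0 to 1 without 1 replicate.

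Lists called between the final groups, 5, were 1 with total counts, 3 with at least 100 T0 counts, 10 with the median over guides and 1 to 5 without 1 replicate. For the difference of the changes, 5 became 1, 3, 11 and 1 to 6 in the same order. At T0, 1 became 0 with olfactory guides, 0 without a filter, 0 with at least 100 counts, 0 with the median over guides and 0 to 2 without 1 replicate. The area under the ROC curve in DMSO was 0.884 without a filter, 0.751 with at least 100 counts, 0.830 with the median over guides and 0.876 with crossed T0 arms; in enzalutamide it was 0.856 and 0.761 for the first 2. At equal total counts, guides at 0 were 0.558% in DMSO T0, 0.549% in enzalutamide T0 and 2.78% in DMSO final. The ratio of guides under 10 counts was 4.14 in the full libraries and 3.27 at equal total counts.

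Named genes kept direction and side of the threshold, or without a call stayed within the SD over label pairs or, between arms, over the enzalutamide values alone, in 220 settings between the final groups (9 lost the call, 10 without a call moved further), 336 in DMSO (19 lost, 6 gained, 7 moved), 327 in enzalutamide (30 lost, 10 moved) and 63 for the difference (95 lost). Lists kept their side of the threshold in 119 (14 lost, 7 gained), 323 (6 lost, 1 gained), 311 (8 lost, 11 gained) and 209 (13 lost, 9 gained). The final libraries of one number in both arms had correlations of -0.00130 to 0.00399, so the number gave no pairing there. Smaller sets of guides, genes or libraries follow from the filters and left-out replicates; other causes were not tested. At a median of 33 reads per guide in enzalutamide final, a fall below the floor of 3 counts cannot be measured.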

Other observations

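The tests of guides without a target, of the very high guides in enzalutamide T0 replicate 1, of the window on chromosome 12 and the minimum of 10 genes per window were chosen only after the result was seen.

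Expanded guides were counted per gene. A guide in a final library more than 10-fold above the mean of the 6 T0 libraries was counted as expanded, which held for 5.35% of guides and libraries in enzalutamide and 2.12% in DMSO. ARRDC3 had 6 of 12 combinations (binomial test, adjusted p = 0.115), CDKN1B, a brake of cyclin-dependent kinases, 5 of 12 (0.552) and RB1 3 of 12, and these 3 did not pass. FBXO42, chosen after its values were seen, was at 4.11 ± 1.06 between the final groups (adjusted p = 0.931 in edgeR with rank aggregation), CDKN1B at 2.64 ± 3.18 and BCL2 at 2.52 ± 1.43.

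Neighbouring genes changed together. The hypothesis was that copy number contributes, because a guide makes more breaks where a region is amplified. The variance of the medians of 890 windows of 20 genes in DMSO was above 100% of 1000 shuffles, with a ratio of 1.73 to the median shuffle, and it was 1.67 in enzalutamide, 1.21 between the final groups and 1.45 at T0, where no knockout time differs. Neighbours also share function, so copy number may be 1 contributor among others; no copy number data were at hand. The lowest window in DMSO lay on chromosome 16 from 2487476 to 3021573 (-0.70), in enzalutamide on chromosome 3 from 127321629 to 128970662 (-1.25, with GATA2 and MCM2), and the highest in enzalutamide on chromosome X from 100880116 to 102755253 (1.26, with ARMCX, BEX and TCEAL genes). Between the final groups the lowest lay on chromosome 2 from 95539943 to 97215774 (-0.98) and the highest on chromosome 12 from 13063374 to 15099478 (0.84; 0.31 in DMSO and 1.22 in enzalutamide).

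The median log2 change from the mean of the 6 T0 libraries was higher for control than for olfactory receptor guides in 5 of 6 final libraries. The difference was 0.19 ± 0.11 in DMSO and 0.22 ± 0.56 in enzalutamide (n = 3). This is a change and not a level, since at T0 the median log2 CPM was 3.03 for control and 3.25 for olfactory receptor guides. The idea that guides without a target fare better is left open by the 1 library that went the other way. In enzalutamide T0 replicate 1, 58 guides of 58 genes were more than 10-fold above the other T0 libraries and held 2.35% of its reads. In the final libraries of number 1 their median was 0.940 of the typical guide in DMSO and 0.458 in enzalutamide, which argues against clones that had expanded by T0.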
